A study of Mus musculus with 10 samples.

How the data were processed

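Splenic cDC2 had been sorted, after digestion of spleens with Collagenase B and DNase and enrichment of CD11c+ cells, and their RNA was labelled with biotin by the Ambion WT kit and hybridised to Affymetrix Mouse Gene 1.0 ST arrays. The deposited values are intensity on a linear scale, normalized between arrays by the authors; the normalization method is not given in the sources used here. The table held 28853 probe sets on 10 arrays with no missing value and none at or below 0. Array medians lay between 29.5 and 31.7 and the values between 2.57 and 11436.78. No detection p-values were used, so no gene was called above background. Nothing in the labels says that replicates came from separate mice, so the spread between them may be technical in part.

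Values were log2 transformed. Of the probe sets 21789 listed exactly 1 gene symbol, 1621 several and 5443 none; for each of 19938 genes the probe set with the highest mean over the 10 arrays was used (999 genes had more than 1), with no filter on dim genes. One limma fit with a mean for each of the 4 groups (lmFit, eBayes with a mean-variance trend; 6 residual and 5.25 prior degrees of freedom) gave 5 comparisons: the SRBC response in each genotype, Notch2KO relative to WT in untreated and in SRBC-treated mice, and the interaction (the Notch2KO response minus the WT response). Tests were two-sided and adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. All p-values of genes in the text are limma's adjusted p.

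Gene lists, 31 with 655 entries of which 588 were measured, covered Notch targets, cDC2 subsets, DC identity and maturation, antigen presentation, chemoattractant receptors, cytokines, NF-kB, interferons, iron, phagocytosis, lipids, the cell cycle, metabolism, protein folding, ribosomes, dissociation stress and markers of 9 other cell types. They were tested with camera at its preset correlation of 0.01, adjusted over the 31 lists of a comparison, with an estimated correlation and fry as alternatives. The lists, the comparisons, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named, in each comparison, the 8 largest rises and the 8 largest falls past the threshold with every array of 1 group above every array of the other (not asked of the interaction), up to 4 members with the smallest p of each list described, and 19 genes whatever their p; clone and predicted genes, small RNAs, olfactory receptors, antigen receptor segments, histones, XIST and Y-linked genes were left out of the largest changes. Members of small counts given by name outside this rule were chosen after their values were seen.

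Responses were compared across genes by Pearson r, Spearman rho and the overlap of calls beside that expected of independent lists. For comparisons that share control arrays, 100 simulations of unchanged groups gave the correlation that sharing alone produces, and the comparison was repeated with 1 WT untreated array for each. Alternatives were the mean of all probe sets of a gene, all probe sets by ID, only genes above the median level, quantile normalization, centring of arrays, no mean-variance trend, a robust variance model, array weights, only the groups compared, the replicate number as a block, a change of at least 2-fold, and leaving out each array in turn. Leaving out both arrays that stood apart, the mean of 22 immediate-early genes as a covariate, and the split of the WT untreated arrays were added after the data were seen, as were the heat shock and monocyte and macrophage sets behind the scores and the gene families.

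On simulated data with 100 genes changed by log2 1 and 100 by log2 2, the fit recovered 72% and 98% of them in the WT response, 66% and 96% in the Notch2KO response, 58% and 96% between untreated genotypes, 79% and 99% between genotypes after SRBC and 35% and 90% in the interaction. Unchanged genes made up between 2.27% and 7.06% of calls. A list shifted by log2 1 was found in each comparison, and none of the 30 other lists was called. Genes were drawn independently of each other there, so the simulation does not show how often camera at its preset calls a list of correlated genes. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.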

Results

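Transcripts of splenic type 2 conventional dendritic cells (cDC2, the CD4-expressing antigen-presenting subset that primes helper T cells) were measured on 10 one-colour arrays. The cells came from wild-type (WT) mice or from mice in which CD11c-Cre acts on floxed alleles of Notch2, called Notch2KO here after their genotype label. Mice were untreated or had received 200000000 sheep red blood cells (SRBC, a particulate antigen used to raise germinal centre responses in the spleen) intraperitoneally 24 hours earlier. WT untreated and Notch2KO untreated had 2 arrays each, and WT SRBC and Notch2KO SRBC had 3 each. The median intensity of an array lay between 29.5 and 31.7, and the number of arrays limits the precision. Values are log2 differences ± the standard error of the fit, on these n, unless another error is named.

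Genotype was the largest source of variance. The first principal component of the 9969 brighter genes held 43.1% of it and separated the genotypes, and the second held 26.8% and placed every untreated array above every SRBC array. Pearson r between arrays of a group was 0.991 in WT untreated and 0.989 in Notch2KO untreated. WT SRBC 1 stood apart from both other WT SRBC arrays (r 0.971 and 0.971, against 0.990 between those). Notch2KO SRBC 3 stood apart from its group in the same way (r 0.978 and 0.975, against 0.988).

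The signal of Notch2 itself was not lower in the Notch2KO arrays. Its log2 intensity was 8.13 ± 0.02 (SD, n = 2) in WT untreated, 8.27 ± 0.14 (SD, n = 2) in Notch2KO untreated, 7.26 ± 0.28 (SD, n = 3) in WT SRBC and 7.61 ± 0.37 (SD, n = 3) in Notch2KO SRBC. The genotypes did not differ past the threshold without treatment (0.14 ± 0.26, adjusted p = 0.915) or after SRBC (0.35 ± 0.21, adjusted p = 0.455). One probe set summarises the gene, and the labels do not say which part Cre removes, so this level does not check the genotype labels. Transcripts downstream of Notch did differ. Hes1, a repressor that Notch induces directly, was lower in untreated Notch2KO cells (-2.60 ± 0.26, adjusted p = 0.000143), as was Dtx1, encoding the Notch regulator Deltex1 (-2.41 ± 0.33, adjusted p = 0.00122). The other 9 of the 11 Notch pathway genes did not pass, and the list did not move as a whole (camera, adjusted p = 0.197).

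**Figure D1:**
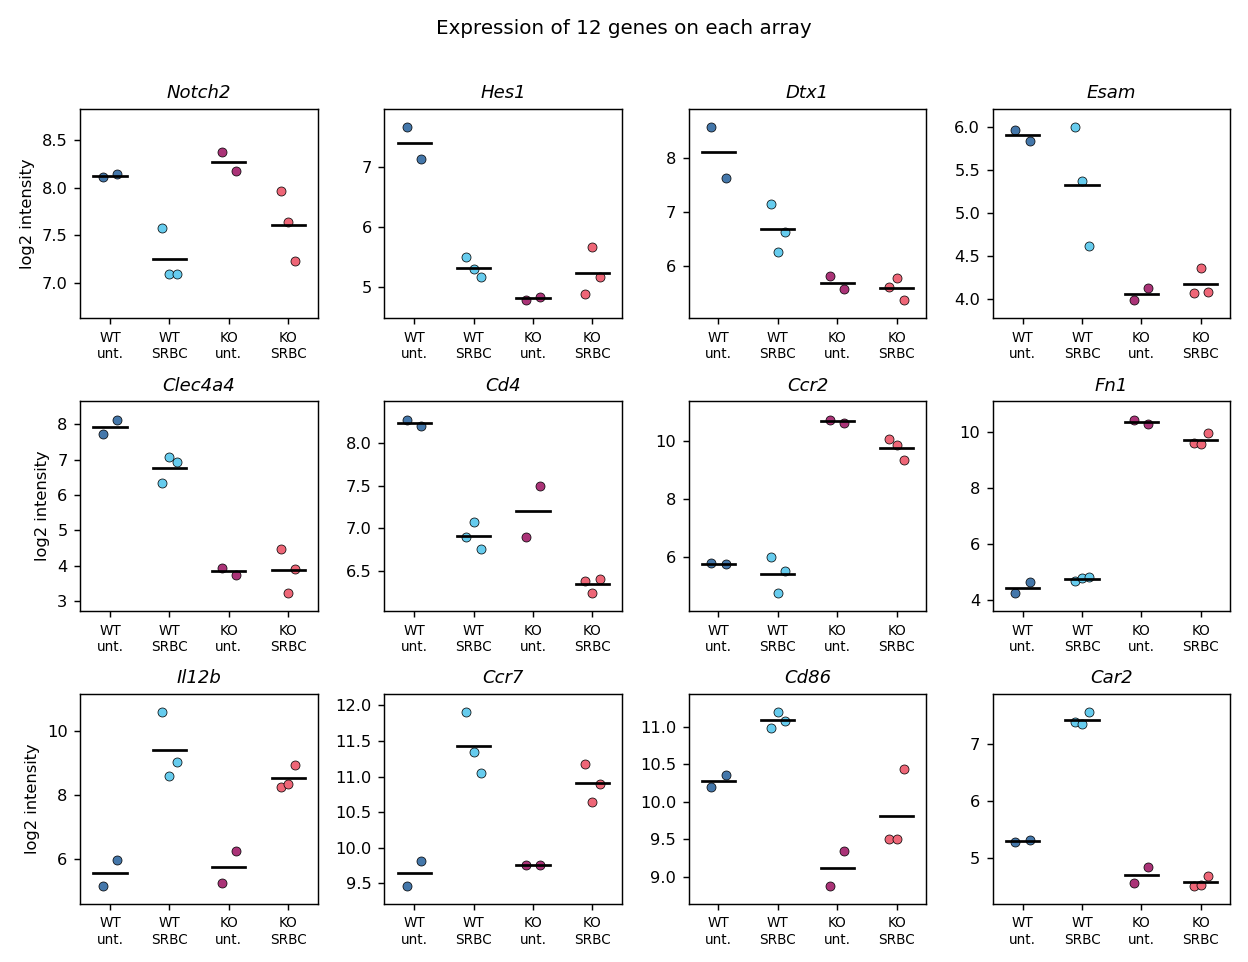
Log2 intensity of 12 genes on each of the 10 arrays (points) in the 4 groups, with a line at each group mean; axes differ between panels. Hes1 in untreated WT lay at 7.41 against 4.81 in untreated Notch2KO, and Ccr2 at 5.79 against 10.66.

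The first comparison asked how Notch2KO cDC2 differed from WT cDC2 in untreated spleens. Genes of the ESAM-low, monocyte-like cDC2 subset were higher in Notch2KO, and those of the ESAM-high subset, which depends on Notch2, were lower. Fn1, encoding fibronectin, rose most (5.92 ± 0.21, 60.4-fold, adjusted p = 1.92e-07; n = 2 and 2), and Ccr2, the receptor by which monocytes leave the marrow, rose by 4.87 ± 0.35. The endocytic lectins Mgl2 (5.52 ± 0.33), Clec10a (5.0 ± 0.27) and Mrc1 (5.32 ± 0.53), the lipase Lpl (5.17 ± 0.25) and the scavenger receptor Cd36 (5.12 ± 0.37) were among the 8 largest rises, with Tnip3 (4.91 ± 0.33) and the actin-capping Capg (4.88 ± 0.33). Dnase1l3, a secreted DNase of dendritic cells, fell most (-5.92 ± 0.28, adjusted p = 1.52e-06), followed by Adgrl3 (-4.11 ± 0.29) and Clec4a4, which encodes the cDC2 lectin DCIR2 (-4.09 ± 0.35). Slc12a2 (-3.69 ± 0.21), Cd7 (-3.69 ± 0.54), Arap2 (-3.66 ± 0.37), Stra6l (-3.64 ± 0.26) and the efflux pump Abcb1a (-3.57 ± 0.36) completed the 8 largest falls.

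All 12 measured ESAM-low genes rose, among them Lyz1 (4.32 ± 0.23), Cx3cr1 (3.12 ± 0.47) and Ccr2 (list mean 3.56, adjusted p = 2.69e-31, and adjusted p = 0.00429 with an estimated correlation). Of the 7 ESAM-high genes 5 fell over all genes and 6 adjusted over the list alone: Clec4a4, Dtx1, Esam (-1.84 ± 0.33), Cd4 (-1.03 ± 0.22) and the T-box factor Tbx21 (-1.04 ± 0.22) were the 5 (adjusted p = 1.95e-08, and adjusted p = 0.00843 with an estimated correlation). Both lists follow published descriptions of the subsets in Notch2-deficient spleens and were, as far as known, not drawn from these arrays. Of 15 genes of conventional DC identity, the receptor Kit (-2.27 ± 0.24) and the transcription factor Bcl11a (-1.67 ± 0.39) fell, Irf8 rose (1.93 ± 0.36) and 12 did not pass, including Zbtb46 (-0.42 ± 0.21), Itgax (0.34 ± 0.25) and Irf4 (-1.49 ± 0.39, adjusted p = 0.0528). Gpr183, the oxysterol receptor that positions cDC2 in the spleen, fell by 1.55 ± 0.19 (adjusted p = 0.000596).

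Genes of uptake and degradation were higher in untreated Notch2KO. Of 29 phagocytosis and lysosome genes 14 rose and none fell, with 19 higher adjusted over the list alone, led by the Fc receptor Fcgr3 (4.51 ± 0.29), the phosphatidylserine-recognising kinase Axl (3.62 ± 0.30) and the inhibitory Fcgr2b (3.10 ± 0.31; list adjusted p = 0.00843 with an estimated correlation). Heme and iron genes moved both ways, with 6 of 23 higher and 2 lower: heme oxygenase Hmox1 (3.19 ± 0.43), the hemoglobin scavenger Cd163 (1.47 ± 0.25) and Blvrb (1.56 ± 0.27) rose, while the transferrin receptor Tfrc fell (-2.07 ± 0.27; list adjusted p = 0.0496 with an estimated correlation). Of 11 liver X receptor (LXR) targets 4 rose, including Smpdl3a (2.24 ± 0.23) and Apoe (1.78 ± 0.28; adjusted p = 0.0407 with an estimated correlation). Of 17 interferon-gamma-responsive genes 5 rose, including Cxcl9 (2.74 ± 0.26) and the guanylate-binding proteins Gbp3 (2.62 ± 0.30) and Gbp7 (2.03 ± 0.21; adjusted p = 0.0426 with an estimated correlation). Markers of other cells moved with these groups: 10 of 18 macrophage markers rose, among them C1qa (2.46 ± 0.21) and C1qc (2.98 ± 0.34). Likewise 6 of 14 monocyte markers rose and Treml4 fell, with Lyz2 (2.68 ± 0.20) and Csf1r (2.24 ± 0.21) among those higher (adjusted p = 0.0426 for macrophages and 0.00843 for monocytes with an estimated correlation). The macrophage list shares Axl, Hmox1, Cd163 and others with the lists above, and 4 of the 6 monocyte markers (Ccr2, Csf1r, Cx3cr1 and Lyz2) are also ESAM-low genes, so neither call is separate from those. Of 13 markers of type 1 conventional dendritic cells, Clec9a (3.00 ± 0.50), Naaa (2.33 ± 0.34), Cadm1 (1.72 ± 0.21) and Irf8 rose and Wdfy4 fell (-2.01 ± 0.22). This list's call was lost without WT untreated 1 (adjusted p = 0.0731) and without Notch2KO untreated 2 (adjusted p = 0.0964), and adjusted p = 0.129 with an estimated correlation.

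Cytokines and chemokines had 6 of 24 members higher and none lower, with Ccl22 (4.49 ± 0.34), Cxcl2 (4.57 ± 0.52), Ccl17 (2.64 ± 0.38) and Il6 (2.90 ± 0.50) among them. Of 14 genes of NF-kB feedback 4 rose, including Nfkbia (1.75 ± 0.21; adjusted p = 0.129 for both lists with an estimated correlation). Of 33 division genes of the G2 and M phases 16 fell and none rose, with 26 lower adjusted over the list alone, such as Bub1 (-1.66 ± 0.22), Cenpf (-1.46 ± 0.22) and Top2a (-1.51 ± 0.29; adjusted p = 0.0913 with an estimated correlation). Of 26 S phase genes 6 fell, including the ribonucleotide reductase subunit Rrm2 (-1.36 ± 0.24; adjusted p = 0.0663 with an estimated correlation). Of 17 glycolysis genes 4 rose, among them Aldoa (1.64 ± 0.33; adjusted p = 0.129 with an estimated correlation). The maturation list had Ccl22, Ccl17 and Tnfsf9 (1.86 ± 0.29) higher and the costimulatory ligand Cd86 lower (-1.16 ± 0.29), and its call ended without Notch2KO untreated 2 (adjusted p = 0.057) and with an estimated correlation (adjusted p = 0.435). Chemoattractant receptors had 4 of 20 members higher, such as Ccr1 (3.23 ± 0.28), and 3 lower, and the call ended without WT untreated 1 (adjusted p = 0.0827) and with an estimated correlation (adjusted p = 0.129). Camera also called small mean rises of cholesterol synthesis (0.18, although Srebf2, the only member past the threshold, was lower), oxidative phosphorylation (0.24), the unfolded protein response (0.27) and ribosomal proteins (0.11). Each of these 4 was lost without WT untreated 1 (adjusted p = 0.18, 0.0849, 0.18 and 0.0731). Cholesterol synthesis was also lost without Notch2KO untreated 1 (0.0753) or 2 (0.0676), oxidative phosphorylation without Notch2KO untreated 2 (0.167) and ribosomal proteins without Notch2KO untreated 1 (0.0751), and adjusted p was 0.202, 0.509, 0.285 and 0.503 with an estimated correlation.

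Over all 19938 genes, 1019 differed between the untreated genotypes at an adjusted p below 0.05 (589 higher and 430 lower in Notch2KO), and 20 of 31 lists passed camera (17 up, 3 down), 8 of them with an estimated correlation. The gene count was 418 without WT untreated 1, 474 without WT untreated 2, 447 without Notch2KO untreated 1 and 561 without Notch2KO untreated 2, and 1996 without both SRBC arrays that stood apart. Of 84 named calls, 59 held without WT untreated 1 and 61 without Notch2KO untreated 1. Esam was lost without either (adjusted p = 0.0689 and 0.067), Cd4 without either (0.152 and 0.218) or WT untreated 2 (0.11), and Il6 without WT untreated 2 (0.0609) or Notch2KO untreated 2 (0.0608).

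In the response of WT cDC2 to SRBC, the second comparison, 10 of 25 maturation genes rose, and 8 of 26 immediate-early and dissociation stress genes and 3 of 12 class II presentation genes fell. These lists were called by camera and did not pass with an estimated correlation (adjusted p = 0.159, 0.159 and 0.182). Socs2, a suppressor of cytokine signalling, rose most (4.06 ± 0.41, 16.7-fold, adjusted p = 0.0006; n = 2 untreated and 3 SRBC arrays), followed by Il12b, the shared subunit of IL-12 and IL-23 (3.80 ± 0.52), Cd200 (3.48 ± 0.34) and the endocytic receptor Ly75 (3.44 ± 0.34). Strip2 (3.42 ± 0.43), Flrt3 (3.32 ± 0.37), the actin-severing Scin (3.31 ± 0.49) and the NF-kB inhibitor Tnip3 (3.28 ± 0.30) made up the 8 largest rises. Il6 rose by 3.24 ± 0.46, Cxcr5, the receptor for the follicular chemokine CXCL13, by 2.92 ± 0.21 and Ccr7, which guides dendritic cells to T cell zones, by 1.79 ± 0.24. The chaperones Hsph1 (-4.70 ± 0.25, adjusted p = 9.14e-06), Hspa1a (-4.43 ± 0.54) and Dnajb1 (-3.10 ± 0.30) fell most, with Dnal1 (-2.84 ± 0.29), the clock-controlled Ciart (-2.84 ± 0.25), the immediate-early gene Egr1 (-2.76 ± 0.44), Gpr141 (-2.35 ± 0.47) and Klrb1f (-2.22 ± 0.38).

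Of 25 maturation and costimulation genes 10 rose and none fell, with 14 higher adjusted over the list alone (list adjusted p = 1.89e-11, and adjusted p = 0.159 with an estimated correlation). Tnfrsf4 (OX40, 2.38 ± 0.24), Ccl22 (2.90 ± 0.31) and the costimulatory ligand Cd80 (1.25 ± 0.17) rose, while Cd86 (0.81 ± 0.27) and Cd40 (0.40 ± 0.35) did not pass. Of 12 class II presentation genes 3 fell over all genes and 5 adjusted over the list alone. The 3 were the transactivator Ciita (-1.80 ± 0.37), H2-Oa (-0.90 ± 0.21) and the peptide-loading H2-DMa (-1.29 ± 0.19). The list had adjusted p = 0.182 in camera with an estimated correlation. Of 11 Notch pathway genes Hes1 (-2.09 ± 0.23) and Dtx1 (-1.43 ± 0.30) fell and the list did not pass (camera, adjusted p = 0.0754, and 0.44 with an estimated correlation). Also lower were the ESAM-high genes Cd4 (-1.32 ± 0.20) and Jaml (-1.60 ± 0.39; 3 of 7 lower, adjusted p = 0.105 with an estimated correlation). Clec4a4 (-1.15 ± 0.32, adjusted p = 0.078) and Esam (-0.57 ± 0.30) did not pass. Type I interferon-stimulated genes had 5 of 30 members lower, led by Oas2 (-2.07 ± 0.27) and Ddx58 (-1.32 ± 0.24; adjusted p = 0.281 with an estimated correlation). In the unfolded protein response Atf4 (-0.78 ± 0.16) and Dnajb9 (-0.78 ± 0.19) fell among 24 genes (adjusted p = 0.201 with an estimated correlation). Of 33 G2 and M phase genes Aurka alone fell over all genes (-0.96 ± 0.18) and 8 did adjusted over the list alone (adjusted p = 0.31 with an estimated correlation). No ribosomal protein gene passed, although the list of 35 was called lower (mean -0.21, adjusted p = 0.3 with an estimated correlation).

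Of 26 immediate-early and dissociation stress genes 8 fell, with 17 lower and 1 higher adjusted over the list alone, among them Ier2 (-1.69 ± 0.25; list mean -1.20, adjusted p = 8.92e-12, and adjusted p = 0.159 with an estimated correlation). The mean of 17 heat shock genes was 9.42 and 9.27 in WT untreated and 7.73, 7.85 and 7.81 in WT SRBC. Such genes are known to respond to tissue digestion, by which these cells were obtained. Of 18 macrophage markers 4 rose past the threshold, Vcam1 (1.75 ± 0.25), C1qc (1.72 ± 0.31), the red pulp macrophage factor Spic (2.11 ± 0.42) and Fcna (0.98 ± 0.21), with 10 higher adjusted over the list alone (adjusted p = 0.201 with an estimated correlation). Of the NK cell list Klrk1 rose (1.11 ± 0.27; 1 of 13, adjusted p = 0.116 with an estimated correlation). The erythroid list was called through Car2 (2.13 ± 0.15) and Car1 (1.06 ± 0.26), which encode carbonic anhydrases, and was lost without WT untreated 1 (adjusted p = 0.051) and with an estimated correlation (adjusted p = 0.201).

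**Figure D2:**
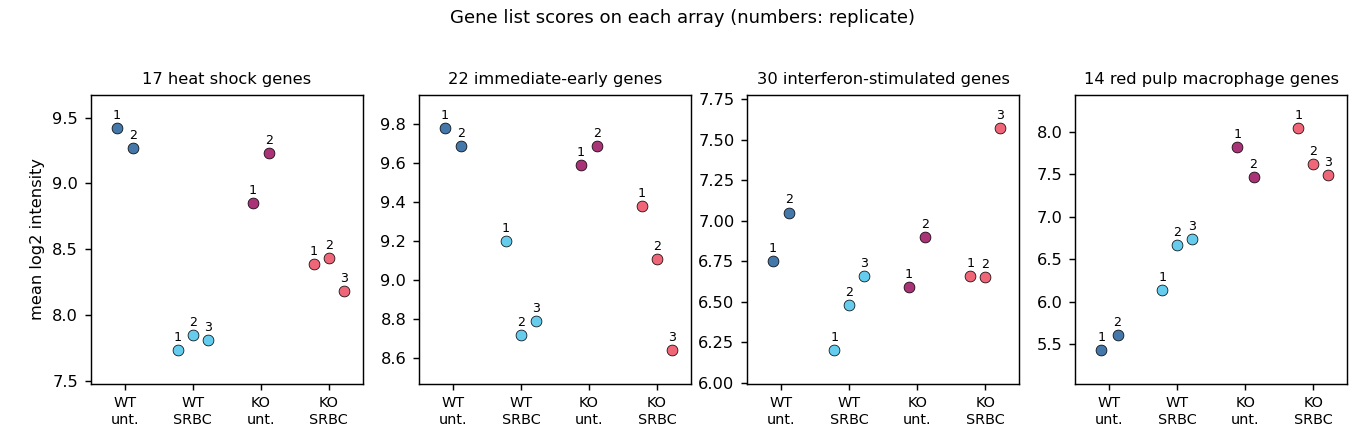
Mean log2 intensity of 4 sets of genes on each array (points, numbered by replicate) in the 4 groups. The heat shock score of WT lay at 9.27 and 9.42 untreated and between 7.73 and 7.85 after SRBC, and Notch2KO SRBC 3 had the highest interferon-stimulated score, 7.57.

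In lists that were not called, single members moved. The T cell list gave Il7r (2.67 ± 0.18) and the B cell list Cd22 (-1.83 ± 0.19) and Bank1 (-1.11 ± 0.21). Itgam (-1.44 ± 0.19) and Bcl11a (-2.19 ± 0.36) fell and Id2 (0.85 ± 0.17) and Irf8 (1.42 ± 0.33) rose among the DC identity genes, and Cd209a fell (-1.83 ± 0.21) while Cd36 (2.06 ± 0.34) and Cd14 (2.68 ± 0.60) rose among the ESAM-low genes. The chemokine Ccl3 fell (-1.87 ± 0.19) and Cxcl16 rose (1.43 ± 0.20). Of the iron and oxidative stress genes Tfrc (-1.51 ± 0.24) and Bach1 (-1.10 ± 0.18) fell and the cystine transporter Slc7a11 rose (2.38 ± 0.48).

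The last 3 called lists had few members past the threshold or none. Chemoattractant receptors (adjusted p = 0.0405) had Cxcr5, Ccr7, Vcam1 and Xcr1 (1.09 ± 0.22) higher among 20, and NF-kB feedback (0.0398) had Traf1 (0.79 ± 0.17) among 14. The receptor list's call ended without WT untreated 1 (adjusted p = 0.0586), without WT SRBC 1 (0.0616) and without Notch2KO SRBC 2 or 3 (0.0522 and 0.0638). The NF-kB list's call ended without WT untreated 2 (0.0855) and WT SRBC 1 (0.106). With an estimated correlation adjusted p was 0.201 for receptors and 0.44 for NF-kB. The S phase list, with no member past the threshold, was called at adjusted p = 0.0498 (0.44 with an estimated correlation). It was lost without each of 5 arrays, WT untreated 2 (0.181), WT SRBC 2 (0.232), WT SRBC 3 (0.0518), Notch2KO SRBC 2 (0.0905) and Notch2KO SRBC 3 (0.0638).

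In all, 756 genes passed (363 higher and 393 lower after SRBC) and 14 of 31 lists were called (6 up, 8 down). None of them was called with an estimated correlation, and fry called 10 lists, 9 of them among the 14. The gene count was 101 without WT untreated 1, 199 without WT untreated 2, 407 without WT SRBC 2, 387 without WT SRBC 3 and 1331 without WT SRBC 1, and it was 256 with the immediate-early score of each array as a covariate, 121 of them among the 756. Of 71 named calls 22 held without WT untreated 1, 36 without WT untreated 2 and 28 with the covariate. Il12b, Ccr7, Il6, Cd80, Cd4 and Dtx1 were lost without WT untreated 1 (adjusted p = 0.069, 0.069, 0.051, 0.0719, 0.0906 and 0.291). Cd4 was also lost without WT untreated 2 (0.0535) and Dtx1 without WT SRBC 2 or 3 (0.0806 and 0.0772), whereas Socs2, Cxcr5 and Hes1 held with any single array left out.

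**Figure D3:**
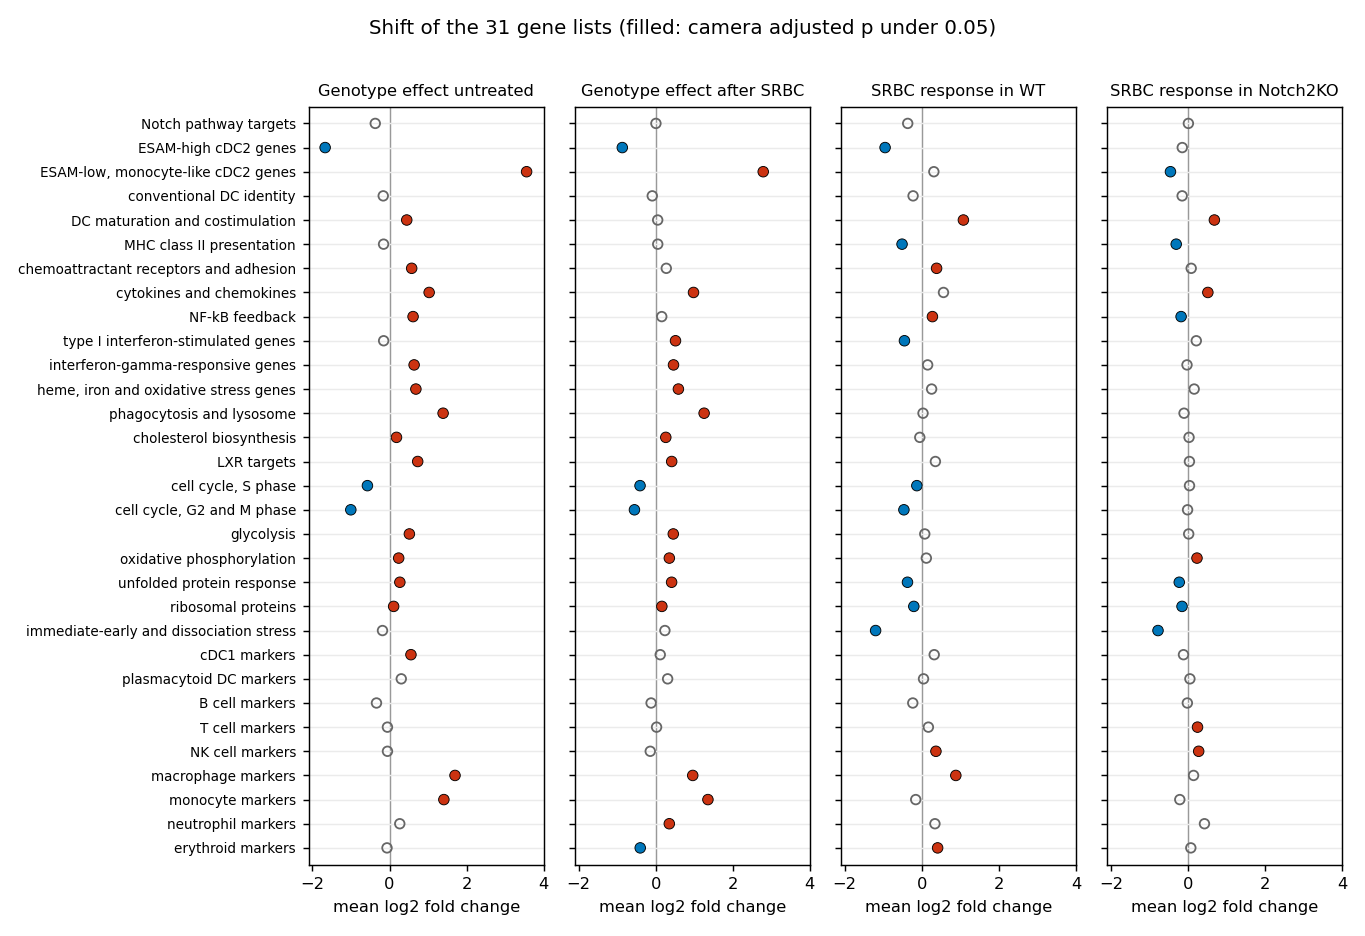
Mean log2 fold change of the 31 gene lists in 4 comparisons (columns); filled points passed camera at an adjusted p below 0.05, red above 0 and blue below 0, and open points did not. The ESAM-low list lay at 3.56 in untreated and 2.79 in SRBC-treated Notch2KO relative to WT.

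The same treatment in Notch2KO, the third comparison, asked how cDC2 of that genotype responded to SRBC. Each array averages the sorted cells, so a different mix of ESAM-high and ESAM-low cells cannot be told apart from a changed response within cells. The neutrophil-type calcium-binding protein gene S100a8, which also rose past the threshold in WT, rose most (3.06 ± 0.46, 8.37-fold, adjusted p = 0.0263; n = 2 and 3). It was followed by Serpinb6b (2.58 ± 0.24), Socs2 (2.45 ± 0.41), Cd200 (2.26 ± 0.34), Ly75 (2.11 ± 0.34), the prion protein gene Prnp (2.02 ± 0.26), the IL-2 receptor subunit Il2ra (1.91 ± 0.33) and Gria3 (1.86 ± 0.24). Hsph1 fell most (-3.01 ± 0.25, adjusted p = 0.000945), followed by the transcriptional regulator Id3 (-2.04 ± 0.28), Ciart (-1.89 ± 0.25), Mgl2 (-1.84 ± 0.30), Dnajb1 (-1.76 ± 0.30), Dnal1 (-1.66 ± 0.29), Calhm2 (-1.62 ± 0.22) and Bicra (-1.53 ± 0.27). Cxcr5 rose (1.17 ± 0.21, adjusted p = 0.0483), while Il12b (2.75 ± 0.52, adjusted p = 0.0585), Il6 (2.40 ± 0.46, adjusted p = 0.0614) and Ccr7 (1.14 ± 0.24, adjusted p = 0.0895) did not pass.

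Of 25 maturation genes Socs2 and Cd200 passed over all genes and 9 were higher adjusted over the list alone (mean 0.68, adjusted p = 1.6e-07, and adjusted p = 0.262 with an estimated correlation). Of 12 ESAM-low genes 3 fell, Mgl2, Clec10a (-1.46 ± 0.25) and Cd209a (-1.49 ± 0.21; adjusted p = 0.207 with an estimated correlation). Of 26 immediate-early and stress genes 4 fell, including Ier2 (-1.50 ± 0.25) and Zfp36 (-0.96 ± 0.17; adjusted p = 0.244 with an estimated correlation). The heat shock score in Notch2KO was 8.85 and 9.23 without treatment and 8.39, 8.43 and 8.18 after SRBC. No class II gene passed and 3 of 12 were lower adjusted over the list alone (list mean -0.31, adjusted p = 0.262 with an estimated correlation), and the ribosomal list was called lower with no member past the threshold (mean -0.16, adjusted p = 0.402 with an estimated correlation). The cytokine list had Ccl3 lower (-1.14 ± 0.19) although its mean was 0.51, and this call was lost without Notch2KO SRBC 3 (adjusted p = 0.638) and with an estimated correlation (adjusted p = 0.447). Of the cholesterol genes Idi1 rose (1.59 ± 0.21), and of the neutrophil markers S100a8 rose. Notch2KO SRBC 3 held the highest interferon-stimulated score of all arrays (7.57, against 6.66 and 6.65 on the other arrays of its group).

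Lists of NF-kB feedback (mean -0.18), oxidative phosphorylation (0.23), the unfolded protein response (-0.23), T cells (0.25) and NK cells (0.28) were called with no member past the threshold over all genes. The NF-kB call was lost without Notch2KO untreated 2 (adjusted p = 0.0764) and Notch2KO SRBC 2 (0.451), oxidative phosphorylation without Notch2KO untreated 1 (0.394) and Notch2KO SRBC 3 (0.101), and the unfolded protein response without Notch2KO SRBC 2 (0.0645). The T cell call was lost without Notch2KO SRBC 1 (0.0509) and 2 (0.0645), and the NK cell call without Notch2KO untreated 2 (0.0764). With an estimated correlation, adjusted p was 0.447, 0.665, 0.388, 0.267 and 0.207 for these 5 lists.

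In Notch2KO 61 genes passed (28 higher and 33 lower), against 1994 at an unadjusted p below 0.05, and 11 lists were called (5 up, 6 down), none with an estimated correlation or by fry. The gene count was 2 without Notch2KO untreated 1, 11 without Notch2KO SRBC 1, 13 without Notch2KO untreated 2, 26 without Notch2KO SRBC 2, 27 without either WT untreated array, 31 without WT SRBC 3 and 183 without WT SRBC 1, and 398 without both arrays that stood apart. Of 23 named calls 1, that of Hsph1, held without Notch2KO untreated 1, and Socs2, S100a8 and Cxcr5 did not (adjusted p = 0.389, 0.286 and 0.228). These 3 were lost without 7, 5 and 8 of the 10 arrays in turn. Leaving out an array outside a comparison changes only the estimate of spread and its degrees of freedom. Without WT untreated 1 the log2 changes of Socs2, S100a8 and Cxcr5 in Notch2KO thus stayed at 2.446, 3.065 and 1.172. With the immediate-early covariate 25 genes passed, 11 of them among the 61, and 4 of the 23 named calls held.

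The fourth comparison set the genotypes side by side 24 hours after SRBC. Fn1 (4.96 ± 0.17, 31.2-fold, adjusted p = 1.42e-07; n = 3 and 3), the guanine deaminase Gda (4.51 ± 0.42), Lpl (4.44 ± 0.21), Ccr2 (4.29 ± 0.29), the adhesion receptor Cd226 (4.17 ± 0.27) and the chemokines Ccl6 (4.12 ± 0.17), Cxcl13 (4.03 ± 0.29) and Ccl9 (4.0 ± 0.18) were higher in Notch2KO by the most. Dnase1l3 (-4.81 ± 0.23, adjusted p = 9e-07), Arap2 (-3.20 ± 0.30), the mitochondrial coactivator Ppargc1a (-3.03 ± 0.24), Abcb1a (-3.02 ± 0.30), Clec4a4 (-2.91 ± 0.29), Havcr2, which encodes TIM-3 (-2.89 ± 0.32), Car2 (-2.85 ± 0.13) and Klri2 (-2.67 ± 0.21) were lower by the most. The costimulatory ligands Cd86 (-1.27 ± 0.24) and Cd80 (-0.71 ± 0.15) and the receptors Cxcr5 (-1.60 ± 0.19) and Ccr6 (-1.55 ± 0.15) were lower in Notch2KO, and Il6 was higher (2.06 ± 0.41). Il12b (-0.88 ± 0.46, adjusted p = 0.371), Ccr7 (-0.53 ± 0.21, adjusted p = 0.225), Gpr183 (-0.54 ± 0.16, adjusted p = 0.0752) and Hes1 (-0.09 ± 0.21, adjusted p = 0.892) did not pass.

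All 12 ESAM-low genes were again higher (mean 2.79, adjusted p = 7.55e-28, and adjusted p = 0.00534 with an estimated correlation). Of 7 ESAM-high genes 4 were lower, Clec4a4, Tbx21 (-0.90 ± 0.18), Esam (-1.15 ± 0.27) and Dtx1 (-1.08 ± 0.27; list adjusted p = 0.0575 with an estimated correlation and 0.0738 without both arrays that stood apart). Of 29 phagocytosis and lysosome genes 17 were higher, including the proteases and hydrolases Ctsd (2.76 ± 0.21) and Hexa (1.85 ± 0.14), and Fcgr3 (3.42 ± 0.23; adjusted p = 0.00534 with an estimated correlation). Of the monocyte markers 6 of 14 were higher (adjusted p = 0.00534 with an estimated correlation), with Lyz2 at 2.59 ± 0.16. Macrophage markers moved with them, 10 of 18 higher, among them C1qa (1.79 ± 0.17), Mrc1 (3.42 ± 0.44) and Axl (2.10 ± 0.25; adjusted p = 0.0923 with an estimated correlation). Neutrophil markers had Csf3r (0.93 ± 0.15) and S100a8 (1.59 ± 0.41) higher among 15, a call lost without Notch2KO SRBC 2 (adjusted p = 0.052) and with an estimated correlation (adjusted p = 0.217). Of 10 erythroid markers Car2 was lower, and the list was lost without WT SRBC 2 (adjusted p = 0.061), without Notch2KO SRBC 3 (0.124) and with an estimated correlation (adjusted p = 0.188).

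Of 24 cytokines and chemokines 7 were higher and none lower, with Ccl17 (3.66 ± 0.31), Ccl22 (2.04 ± 0.28) and Cxcl1 (1.31 ± 0.24; adjusted p = 0.0715 with an estimated correlation). Heme and iron genes had 8 of 23 higher, including Blvrb (1.64 ± 0.22), Hmox1 (1.91 ± 0.35) and Gclc (0.90 ± 0.20; adjusted p = 0.0575 with an estimated correlation). Interferon-gamma-responsive genes (5 of 17 higher, such as Gbp3, 2.10 ± 0.25, and Cd274 lower) and LXR targets (4 of 11 higher, such as Abca1, 1.77 ± 0.38, and Apoe, 1.52 ± 0.23) each had adjusted p = 0.0923 with an estimated correlation. The unfolded protein response had 6 of 24 higher, including Pdia4 (1.53 ± 0.21) and Canx (0.77 ± 0.16; adjusted p = 0.0923 with an estimated correlation). Cholesterol synthesis had Fdft1 (0.95 ± 0.20), Idi1 (0.87 ± 0.19) and Ebp higher and Pmvk lower (-1.30 ± 0.16) among 20, and glycolysis had no member past the threshold over all genes and 4 higher adjusted over the list alone (adjusted p = 0.0923 for both lists with an estimated correlation). Oxidative phosphorylation (mean 0.35) and ribosomal proteins (0.16, with Rpl28 higher by 0.41 ± 0.10) were also called, at adjusted p = 0.296 and 0.258 with an estimated correlation and 0.206 and 0.207 without both arrays that stood apart. Of 33 division genes of the G2 and M phases 7 were lower, such as Bub1 (-1.20 ± 0.18) and Ncapg (-0.91 ± 0.20). Among 26 S phase genes Rrm2 (-0.95 ± 0.20) and Mcm4 (-0.77 ± 0.19) were lower (adjusted p = 0.211 and 0.108 for these 2 lists with an estimated correlation). Of 30 interferon-stimulated genes Bst2 (1.48 ± 0.23) and Cmpk2 (0.63 ± 0.12) were higher, and the list's call (mean 0.51) was lost without Notch2KO SRBC 3 (mean 0.21, adjusted p = 0.0742) and with an estimated correlation (adjusted p = 0.247).

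Some lists not called in either genotype comparison held single members past the threshold. Class II presentation had H2-Ob (-2.00 ± 0.31 untreated, -1.08 ± 0.26 after SRBC) and H2-Oa (-1.34 ± 0.23 and -0.74 ± 0.19) lower, and H2-DMa higher after SRBC (1.40 ± 0.17). The plasmacytoid DC list had Cox6a2 (1.38 ± 0.29) and Tcf4 higher and Tlr7 (-1.64 ± 0.26) lower without treatment (list adjusted p = 0.112). Of the B cell list Cd22 (-2.68 ± 0.21) and Bank1 (-2.13 ± 0.24) were lower without treatment. Of the T cell list Il7r was higher (2.14 ± 0.20) and Cd5 lower (-1.47 ± 0.28) in that comparison. The NK cell list had Klrk1 higher (1.66 ± 0.30) and Klrd1 lower (-0.68 ± 0.17) without treatment, and after SRBC 3 of its 13 members were lower and none higher (camera, adjusted p = 0.137, and 0.0125 by fry).

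After SRBC, 1061 genes differed between the genotypes (670 higher and 391 lower in Notch2KO) and 19 of 31 lists were called (15 up, 4 down), 3 of them with an estimated correlation. The gene count was 649 without Notch2KO SRBC 1, 684 without WT SRBC 2 and 2364 without both arrays that stood apart, where the immediate-early score also followed genotype (8.72 and 8.79 in WT, 9.38 and 9.11 in Notch2KO). Of 78 named calls 62 held without Notch2KO SRBC 1 and 65 without WT SRBC 2. Cd86 and Cxcr5 held with any single array left out. Il6 was lost without WT SRBC 2 (adjusted p = 0.0526), Cd80 without WT SRBC 2 (0.0884) or Notch2KO SRBC 2 (0.0641), and Esam, Dtx1 and S100a8 without 6, 7 and 6 of the 10 arrays in turn (0.099, 0.108 and 0.17 without Notch2KO SRBC 1). The heat shock score after SRBC also differed, at 7.73, 7.85 and 7.81 in WT and 8.39, 8.43 and 8.18 in Notch2KO.

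The fifth comparison tested directly whether the SRBC response differed between genotypes, and 4 genes passed. Car2, which rose in WT, stayed near its level in Notch2KO (interaction -2.26 ± 0.21, adjusted p = 0.00526; n = 2, 3, 2 and 3), with group means of 5.30, 7.43, 4.71 and 4.58 in WT untreated, WT SRBC, Notch2KO untreated and Notch2KO SRBC. Cd63, a tetraspanin of late endosomes, went from 8.53 to 11.14 in WT and from 11.04 to 11.62 in Notch2KO (-2.03 ± 0.20, adjusted p = 0.00526). Hes1 fell in WT from 7.41 to 5.32 and was 4.81 and 5.23 in Notch2KO (2.51 ± 0.33, adjusted p = 0.0486). Its level in untreated Notch2KO lay below the median of every array (lowest log2 median 4.88), so a fall of the WT size may not be visible there. Rnase2a, an eosinophil-type ribonuclease gene, was 2.43 and 2.56 in WT and 2.52 and 4.18 in Notch2KO (1.53 ± 0.17, adjusted p = 0.0104). In 3 of the groups its intensity lay below the 25th percentile of every array (12.4 to 13.8), where no signal above background is shown, so the size of this change is uncertain. No other named gene passed, and those short of the threshold included Il7r (-1.65 ± 0.26, adjusted p = 0.135), Cxcr5 (-1.75 ± 0.30, adjusted p = 0.146), and Ccl22 (-2.44 ± 0.44, adjusted p = 0.146). Nor did Hsph1 (1.69 ± 0.35, adjusted p = 0.214), Gpr183 (1.00 ± 0.25, adjusted p = 0.336), Il12b (-1.05 ± 0.73, adjusted p = 0.913) and Il6 (-0.84 ± 0.65, adjusted p = 0.931). Of the 31 lists 11 were called by camera (5 up, 6 down), none with an estimated correlation and none by fry. At an unadjusted p below 0.05 the interaction held 1289 genes. Without WT untreated 1 no gene passed, without Notch2KO untreated 1 only 1 did, without Notch2KO SRBC 3 there were 7 and without WT SRBC 1 there were 44, and 604 passed without both arrays that stood apart, where genotype after SRBC again ran along the immediate-early score. Without WT untreated 1 adjusted p was 0.103 for Car2, 0.103 for Cd63, 0.107 for Rnase2a and 0.441 for Hes1. Cd63 and Rnase2a were also lost without Notch2KO untreated 1 (0.0841 for each), Rnase2a without Notch2KO untreated 2 (0.108), and Hes1 without 8 of the 10 arrays in turn.

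Across genes, which are not independent replicates, the responses of the genotypes correlated with Pearson r = 0.563 and Spearman rho = 0.412, on arrays that share no sample. Handling or a day that set treated apart from untreated spleens in both genotypes would enter both responses, and the labels do not give the day. Of the 756 genes called in WT 90.5% had the same sign in Notch2KO, where the median size was 0.388 of that in WT. Of the 61 genes called in Notch2KO 91.8% had the same sign in WT, at a median size of 0.984 of that in Notch2KO. Each ratio is over genes chosen for their size in 1 genotype, which lowers it. The first alone is therefore no measure of a weaker response in Notch2KO. The second is lowered in the same way, so this choice alone does not account for the gap between the ratios. The gap goes with smaller changes in Notch2KO, but the interaction test passed only 4 genes, and the cause of the gap was not tested. Genes higher in both numbered 20 (0.51 expected of independent lists) and those lower in both 19 (0.65 expected). Genotype differences before and after SRBC correlated with r = 0.72 and rho = 0.441, with 380 genes higher in both (19.8 expected), 176 lower in both (8.43 expected) and 1 in opposite directions.

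**Figure D4:**
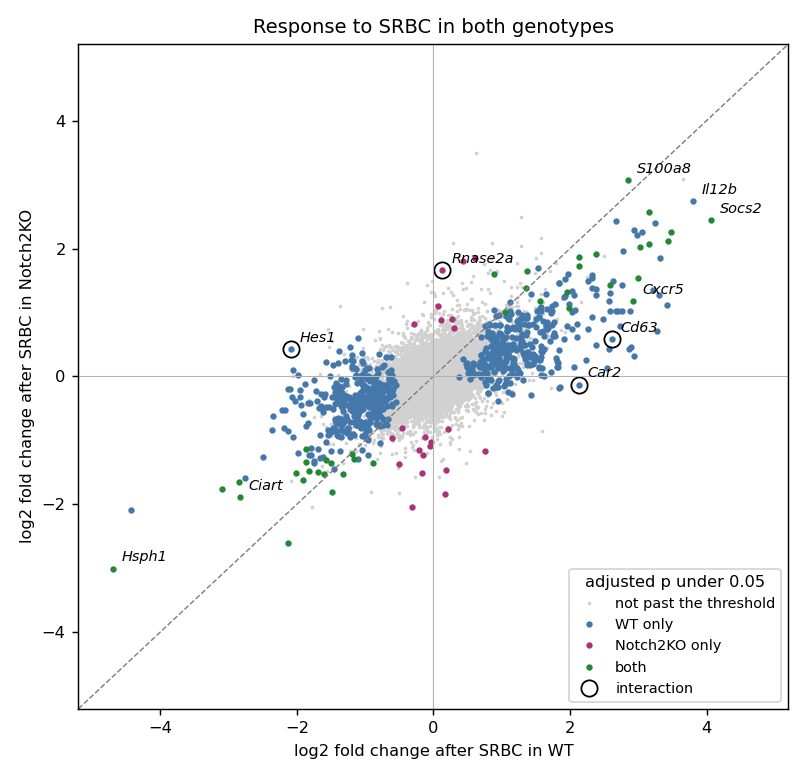
Log2 fold change after SRBC in Notch2KO against that in WT for 19938 genes; colours mark genes past an adjusted p of 0.05 in WT, in Notch2KO or in both, rings the 4 genes of the interaction, and the dashed line equal change. The 39 genes called in both lie in the lower left and upper right, 20 higher and 19 lower.

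The untreated genotype difference was also compared with the WT response across genes. Pearson r was 0.358, below the 0.547 that 100 simulations of unchanged groups gave for comparisons sharing both WT untreated arrays, while the covariance was higher than in these simulations (0.0757 against 0.0303). Changes in 1 comparison alone lower r, so an r below that of unchanged groups does not speak against shared changes. With 1 WT untreated array for each comparison, so that no array was shared, r was 0.262 and 0.257 in both arrangements (rho 0.127 and 0.139, covariance 0.0591 in each). A positive covariance thus remained without shared arrays, although anything common to both WT untreated arrays enters both comparisons.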

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

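Among the tests below, that of red pulp macrophages was written before its result was seen. The tests of handling, of monocytes, of 1 interferon-rich array and of other splits of the arrays were chosen after the results were seen, and both monocyte tests were adjusted after them.

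The interaction test singled out 4 genes whose SRBC response differed between genotypes: Car2 (-2.26), Cd63 (-2.03), Hes1 (2.51, already low in untreated Notch2KO) and Rnase2a (1.53, with dim signal). It also singled out 11 lists by camera: ESAM-high genes (0.80), ESAM-low genes (-0.77), maturation (-0.39), chemoattractant receptors (-0.30), NF-kB feedback (-0.45), interferon-stimulated genes (0.67), S phase (0.17), G2 and M phase (0.45), immediate-early and dissociation stress (0.42), markers of type 1 conventional dendritic cells (-0.44) and macrophage markers (-0.74). None of the 11 passed with an estimated correlation (adjusted p from 0.172 to 0.536) or by fry (0.093 to 0.557). Without single arrays the receptor list (adjusted p up to 0.0739, without WT untreated 1), S phase (up to 0.436, without Notch2KO untreated 1), G2 and M phase (0.102, without Notch2KO untreated 1), the stress list (up to 0.196, without Notch2KO SRBC 1) and the type 1 dendritic cell markers (up to 0.11, without Notch2KO untreated 2) were lost.

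Camera at its preset called the list of interferon-stimulated genes higher after SRBC in Notch2KO relative to WT in the interaction. No member passed on its own, and neither an estimated correlation nor fry gave the call. Notch2KO SRBC 3 had far higher Ifit1 (9.66), Oasl1 (9.38) and Mx2 (7.63) than the other arrays. Without that array the mean interaction was 0.361 (camera at its preset, adjusted p = 0.00127, against 8.52e-07 with it and 2.79e-14 to 0.336 over the alternatives). The list thus stayed called at the preset, but the stricter tests did not call it even with all arrays. Whether that array alone is the cause cannot be decided from this. The mean response of Notch2KO was 0.214 with that array and -0.091 without it. Without it and WT SRBC 1 the mean interaction was 0.241 (adjusted p = 0.0522). The genotype difference after SRBC, 0.514 with all arrays, was 0.21 without Notch2KO SRBC 3 (adjusted p = 0.0742) and 0.089 without both (adjusted p = 0.707), so the size rests largely on those arrays. A biological difference between genotypes stays open and was not tested further.

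A score of 17 heat shock genes, a set chosen after chaperones were seen among the largest falls, changed by -1.547 ± 0.132 after SRBC in WT and -0.702 ± 0.132 in Notch2KO. Of the 17 genes, 11 were lower in WT and 2 in Notch2KO. After SRBC the score was higher in Notch2KO than in WT by 0.537 ± 0.118 (interaction 0.845 ± 0.187), with 95.1% and 94.7% kept under the covariate below. Of the genes 2 passed in the former comparison and none in the latter, so the difference between genotypes rests on the score. Choosing the set after the falls in WT were seen can raise both differences, and their errors do not cover this choice. With the immediate-early score of each array as a covariate the WT change was -1.386 ± 0.232, 89.6% of its size. In Notch2KO it was -0.586 ± 0.191, 83.5% of its size. The slope of this covariate comes from differences between arrays of the same group. Handling that differed between treated and untreated spleens as a whole lies in the group means, so this test cannot decide on it. Treated and untreated spleens may have been processed on different days, which the labels do not give, and this and an effect of SRBC itself cannot be told apart.

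Monocyte-like and macrophage genes were higher in untreated Notch2KO, and other cells in the sorted fraction are a candidate source beside a change of cDC2. A change of cDC2 may lie in the mix of ESAM-high and ESAM-low cells or within cells, which these arrays cannot tell apart. Red pulp macrophage genes outside the fixed list rose by 0.983 ± 0.305 (SE over 8 genes, which are not replicates) against 0.85 needed, within that error of the bound. Of these 8 genes 3 passed, Slc48a1 (1.6), Trf (1.9) and Lrp1 (2.22). Itgad (0.82), Fcgr4 (0.78), Cd68 (0.70), Kcna2 (0.11) and Epor (-0.27) did not. In the fixed list Adgre1 (-0.83, adjusted p = 0.336) and Spic (1.30, adjusted p = 0.18) did not pass either. Of 8 classical monocyte genes, the 4 below the median level of untreated WT differed by 0.758 ± 0.535 on average (median 0.355) against 1.778 needed; only F13a1 passed (2.33), and 4 genes are too few to decide. All 8 averaged 5.87 and 6.12 on the WT untreated arrays and 5.93 and 6.28 on the Notch2KO ones, and Plac8, bright in WT, was lower in Notch2KO (-2.88, adjusted p = 0.00305). Non-classical monocyte genes changed by -0.443 ± 0.487 over 7 genes, none of them below the median level of untreated WT, so a small share would be hidden. The sort for cDC2 is meant to leave such cells out, and the share that remained was not measured.

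The genotypes after SRBC gave 1061 genes, and the highest of the 9 other splits of the 6 SRBC arrays gave 249, with WT SRBC 1 and Notch2KO SRBC 1 and 2 on 1 side, a structure of the samples that follows the immediate-early genes. For lists the real split gave 19 and the highest other 16. In each case 1 of 10 splits, the real one, gave a result as large, and 10 splits are too few for a share under 0.05. Every other split also mixes the genotypes. The genotype difference then enters the spread and lowers the gene count, so these counts do not show what unchanged groups would give. Splits with 0 genes still had up to 16 lists called by camera at its preset.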

How the results depend on the processing

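Leaving out both arrays that stood apart, the immediate-early covariate and the split of the WT untreated arrays were chosen after the data were seen, and the other alternatives before. No named gene reversed; of 260 named calls 243 held under quantile normalization, 254 with centred arrays, 256 with the mean of all probe sets and 162 without WT untreated 1. Named genes were not tested with all probe sets by ID, only genes above the median or the fold threshold. Nor was their interaction in the fit of only the groups compared. In every other gene alternative fixed beforehand 57 of 84 untreated genotype calls held, and 59 of 78 after SRBC. The counts were 21 of 71 in WT, 1 of 23 in Notch2KO and 0 of 4 in the interaction. Lists were tested under quantile normalization, genes above the median, the replicate block, an estimated correlation, fry and each array left out. In all of these 8 of 20, 3 of 19, 0 of 14, 0 of 11 and 0 of 11 lists held, in the same order.

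Counts below are in the order WT response, Notch2KO response, untreated genotypes, genotypes after SRBC and interaction. Array weights (0.371 for WT SRBC 1 and 0.561 for Notch2KO SRBC 3) gave 1886, 267, 1822, 1615 and 63 genes. Without both arrays that stood apart there were 2300, 398, 1996, 2364 and 604. These arrays were chosen because they raise the spread, so leaving them out lowers it by construction. It also leaves immediate-early scores of 8.72 and 8.79 in WT SRBC against 9.38 and 9.11 in Notch2KO SRBC, so that 2364 and 604 mix genotype with a structure along which another split of all 6 SRBC arrays gave 249 genes. The immediate-early covariate gave 256, 25, 1600 (after SRBC) and 13 (interaction). A change of at least 2-fold left 482 genes in WT and 578 between genotypes after SRBC, fewer by construction. The fit of only the groups compared gave 23 in Notch2KO, 1966 between untreated genotypes and 627 after SRBC. No mean-variance trend gave 103 in Notch2KO and 7 in the interaction, all probe sets gave 37 in Notch2KO, and genes above the median gave 2 in the interaction. Quantile normalization left 3 genes in the interaction, 33.3% of them higher. Where no construction is named, the cause was not tested.

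Leaving out each array in turn gave 101 to 1331, 2 to 183, 418 to 1390, 649 to 1256 and 0 to 44 genes, and an arm left with 1 array was assumed to vary like the others. For the interaction, limma gave the 0 without WT untreated 1, against 1289 genes at an unadjusted p below 0.05 with all arrays. Called lists ranged over 12 to 16, 8 to 13, 15 to 22, 18 to 20 and 9 to 13. With an estimated correlation camera called 0, 0, 8, 3 and 0 lists and fry 0 in Notch2KO and 0 in the interaction. The covariate left 7 lists in WT. The labels do not say whether equal replicate numbers share a day. Deviations of equally numbered SRBC arrays correlated across genes, which are not independent replicates, with r = 0.479, -0.218 and 0.403, WT SRBC 2 correlated best with Notch2KO SRBC 3 (0.409), and values of equal numbers with untreated arrays ran from -0.113 to 0.129. The numbers were therefore not taken as pairs, and a shared day stays possible. With the number as a block 715, 50, 1175, 1319 and 6 genes passed, 592, 38, 982, 1026 and 3 of them shared, and 64 of 71, 15 of 23, 83 of 84, 77 of 78 and 3 of 4 named calls held. The interaction of Hes1 was lost (adjusted p = 0.0745).

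The agreement of the SRBC responses was 0.625 for genes above the median, 0.446 to 0.577 without each array, 0.376 without both arrays apart and 0.749 with the covariate. That of the genotype differences was 0.763, 0.657 to 0.723 and 0.581 in the first 3 of these. Under the covariate both SRBC responses are adjusted by the same estimated slope of each gene and share its error, which can raise their agreement. With the covariate, the means reversed for S phase in WT (0.174), oxidative phosphorylation in WT (-0.321) and Notch2KO (-0.083), interferon-stimulated genes in Notch2KO (-0.447) and G2 and M phase in Notch2KO (0.343); the last also reversed without Notch2KO untreated 2 (0.271; -0.295 to 0.271 over single arrays). For cytokines in Notch2KO the direction of the camera test reversed, with a mean still above 0 (0.098). No array carries a background measure, so the limit that dim signal sets was not assessed. Group means of Rnase2a, Cmpk2, Cxcr5, Il6, Mgl2, Clec10a, Ccr1 and Ppargc1a lay below the 25th percentile of every array in at least 1 group, and sizes against such a group are uncertain.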

Other observations

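The families, the clock genes and the tests on them were chosen after the data were seen. Of 160 one-sided Fisher exact tests over 16 families, the C-type lectin receptors stood out among genes higher in untreated Notch2KO, 11 of 33 measured against 0.975 expected (adjusted p = 1.17e-07), among them Clec4a2, Clec4a3, Clec4b1, Clec4d, Clec4e, Clec5a and Clec7a. Chemokines were higher in Notch2KO both untreated (10 of 32, 0.945 expected, adjusted p = 8.98e-07) and after SRBC (13 of 32, 1.08 expected, adjusted p = 1.92e-09), with Ccl2, Ccl6, Ccl9, Ccl24 and Cxcl13 in both. After SRBC, Fc receptors (5 of 13, adjusted p = 0.00116: Fcer1g, Fcgr2b, Fcgr3, Fcgr4 and Fcrls) and S100 proteins (4 of 18, adjusted p = 0.0386) were also higher in Notch2KO. Genes of a family are not independent, so these p-values are lower than they would be for independent genes. Choosing the families after the calls that they count were seen can lower them further.

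Killer cell lectin-like receptors were split in untreated Notch2KO, with Klra2, Klrb1a, Klrb1b and Klrk1 higher (4 of 23, adjusted p = 0.0455) and Klra3, Klrb1f, Klrd1, Klri1 and Klri2 lower (5 of 23, adjusted p = 0.00198). In the WT response 8 of 56 interleukin and TNF receptors rose (1.02 expected, adjusted p = 0.000237: Il15ra, Il21r, Il23r, Il2ra, Il4ra, Il7r, Tnfrsf4 and Tnfrsf9), and after SRBC 6 of 56 were lower in Notch2KO than in WT (adjusted p = 0.0124), among them Il21r, Il23r and Tnfrsf4. Of 15 clock genes Ciart alone changed with SRBC (-2.84 in WT and -1.89 in Notch2KO), while Dbp (-0.30, adjusted p = 0.382, and -0.39, adjusted p = 0.448) and Per1 (-1.22, adjusted p = 0.149, and -1.16, adjusted p = 0.357) did not pass.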
